A study of Mus musculus with 6 samples.

How the data were processed

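Ribosomal-RNA-depleted total RNA libraries were made from CD4+ T cells, the helper lineage of T lymphocytes, of wild-type mice. The labels put 3 samples in a control group and 3 in a group that received 10 mM acetate, and the series' design gives 24 h for both. Nothing in the labels says whether the samples of a group came from separate animals or cultures, so the p-values then measure only the spread between these samples, which may be technical. Per the submitters' processing notes, FastQC 0.11.9, Trim Galore 0.6.6 and STAR 2.6.1d were used with the genome build GRCm39. The counting tool, its strand setting and the annotation release are not given in the sources used here.

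The data analysed here are 1 table of the authors' own comparison, with 1 row per gene and no value per sample. Its title line states that rows are limited to an absolute log2 fold change above 0.5 and an adjusted p under 0.05. The column names are those of a DESeq2 results table, and the authors' testing tool is otherwise not given in the sources used here. The baseMean column, per the file headers, is taken as the mean normalised count over all samples, a signal that joins both groups. The log2 fold change and its standard error, both on the log2 scale, are given as the authors deposited them. The deposited statistic is a score that equals the fold change divided by its standard error in all 6271 rows. The folds were therefore not replaced by shrunken ones after the test. Whether the test itself used shrunken folds is not known. The deposited p-values are 2-sided normal p-values of that statistic, with a largest relative difference of 9.58e-13 on recomputation. The header does not say which group is the numerator of the fold change. Signs are therefore given as positive or negative. Reading a positive fold as higher with acetate follows the order of words in the table's title (with, then without acetate) and is an assumption.

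The number of genes behind the authors' deposited adjusted p-values was recovered from the Benjamini-Hochberg relation between the p-values, their ranks and their adjusted values. It came to 14288, and adjusted values recomputed with it differed from the deposited ones by at most 3.23e-15. The last gene of the table has rank 6271 among all genes tested, so the table holds every gene with an adjusted p under 0.05, and the fold threshold removed none. The names and values of the other 8017 tested genes were not used here. No total count per sample is in the data analysed here, so the depth of each library is unknown and no interval that needs it is given.

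The design fixed before the data were examined called for edgeR's quasi-likelihood test on the authors' counts, with camera and fry for gene lists. These need values per sample and could not be run on the authors' deposited table. The counts of calls are therefore those of that table. Gene lists were tested among its genes. For each of 50 lists fixed before the data were examined, members were matched by symbol or synonym to gene identifiers (a symbol that the reference lacks can match only where the table itself carries it), and lists with at least 5 members in the table were tested. The median log2 fold change of the members was set against 10000 random lists of the same size drawn from the table, matched on 10 equal groups of baseMean. The 2-sided permutation p was adjusted by Benjamini-Hochberg over the 40 lists tested, and the smallest p it can give is 2e-04. This test compares members with other called genes, and takes genes as independent. A correlation between genes cannot be estimated without values per sample, so no list call was checked with one. Each list's calls were also adjusted over the list alone, with members outside the table given a p of 1, which gives the least number that pass.

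A further test, chosen after seeing the data, asked which folds exceeded a common offset. It was a 1-sided Wald test of the deposited fold and standard error against an offset of 0.5 or against the table's median, adjusted over the 14288 genes. It needs no value from outside the table, because genes outside it would have larger p-values. On simulated data with 14288 genes in each of 20 runs and an extra log2 change of 2.00 in 200 genes, it recovered 98.2% of the changed genes with 4.67% false calls, and the number of genes tested was recovered in 20 of 20 runs. A list of changed genes had a permutation p under 0.05 in 20 of 20 runs and a null list in 1 of 20, without adjustment or matching on baseMean. All members of the changed list carried the extra change, so smaller shifts of a list were not tried. The simulated genes were independent and shared 1 offset, which the test was given. In the data the offset is unknown and noise may be shared between genes, so these rates need not carry over.

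Genes were named by a rule fixed before the data were examined. It took the 12 largest positive and the 12 largest negative folds whose symbol is not a gene model, microRNA (mir), snoRNA or pseudogene name, up to 4 members of each list by smallest p, and 12 genes whatever their values. Some genes that the rule names are not reported here. Its minimum of CPM and its requirement that the groups not overlap could not be applied, since both need values per sample. The files' symbols and identifiers were used as deposited. GENCODE release M21, on an earlier genome build than the authors' data, gave gene type, exonic length and GC content for 6260 of the 6271 genes, and none of its coordinates are printed. Genes with near-identical copies, such as Ly6c1, Tubb2a, Tubb2b, Bcl2a1d and the histone genes, can share reads and are less certain. The same holds for genes that overlap on opposite strands, such as mt-Nd6. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.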

Results

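Gene expression was profiled by RNA sequencing of CD4+ T cells from wild-type mice kept for 24 h without acetate (3 control samples) or with 10 mM acetate (3 samples). Acetate is a short-chain fatty acid that cells can turn into acetyl-CoA. The question was how acetate changes the transcriptome of these cells. The data analysed here are the authors' deposited table of genes past their thresholds, which gives each gene's fold change, its standard error (SE) and adjusted p over all samples. It holds no value per sample, so neither the depth of a library nor the values of single replicates can be shown. The spread between replicates enters only through the SE. It does not name the numerator of the fold change either. Folds are called positive or negative as deposited, and a positive fold means higher with acetate only if the fold is acetate over control.

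Nearly all genes that differed between the groups differed in 1 direction. The authors' deposited table lists 6271 genes at an adjusted p under 0.05, of which 6237 have a positive fold and 34 a negative one. These are 43.7% and 0.238% of the 14288 genes that the adjusted p-values show to have been tested. The positive folds were close to one another, with a median log2 fold change of 1.00, which is a fold of 2.00, and quartiles of 0.90 and 1.14. The threshold narrows this range from below: no gene with an absolute statistic under 2.29 is listed, so at the median SE of 0.36 in the authors' deposited table no fold under 0.82 on the log2 scale can appear. Genes in constant use were among them: in the authors' deposited table Actb, the cytoskeletal actin, had a log2 fold change of 0.94 ± 0.36 (SE). Gapdh, a glycolytic enzyme, had 1.07 ± 0.40 and Eef2, the translation elongation factor, 0.96 ± 0.36 in the authors' deposited table (these 3 were chosen after their values were seen). All 3 lie between the quartiles of the positive folds. Among the genes called, all 50 with the highest baseMean were positive, which follows from no negative gene having a baseMean above 196. The baseMean of the other tested genes was not seen.

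The signs depend on the scaling of the libraries, which cannot be redone without counts. A scaling that moves all genes alike leaves the order of the folds as it is. The list comparisons use that order, but only among genes called against no change. Which genes enter them therefore depends on the scaling. Against an offset of 0.5, 99 genes passed a 1-sided Wald test on the authors' deposited folds and SEs, adjusted over all genes tested. Against an offset at the table's median, 7 genes did, namely Il10, Mt3, Mmp9, Vat1, Egr1, Tubb2b and Chst2.

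**Figure D1:**
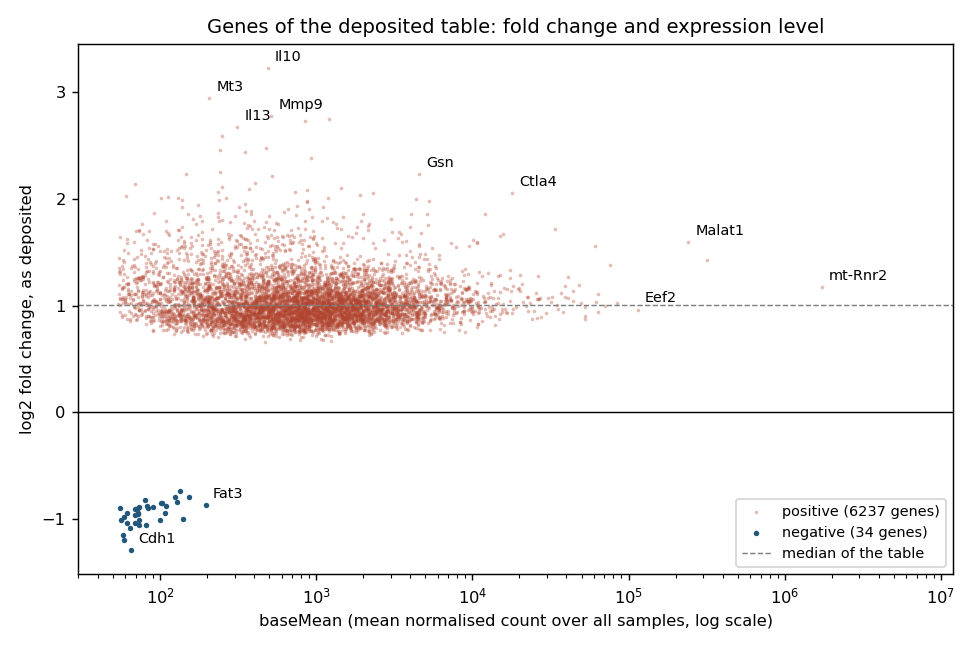
Log2 fold change as deposited (vertical axis) against baseMean, the mean normalised count over all samples (horizontal axis, log scale), with 1 point per gene for 6237 positive and 34 negative genes. Among these genes, which are those past the authors' threshold, the positive ones lie around the dashed median of 1.00 at all expression levels, and the negative genes lie between a baseMean of 55.1 and 196.

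Il10, which encodes an anti-inflammatory cytokine, had the largest fold. Its log2 fold change in the authors' deposited table was 3.23 ± 0.38 (SE), a fold of 9.35, with an adjusted p of 4.63e-13. The metallothionein Mt3 (2.94 ± 0.41), the gelatinase Mmp9 (2.77 ± 0.38) and Vat1 (2.75 ± 0.39), a vesicle membrane protein, came next in the authors' deposited table. The immediate early transcription factor Egr1 followed at 2.73 ± 0.34 (adjusted p = 3.35e-12) and Il13, a cytokine of type 2 immunity, at 2.67 ± 0.45 (adjusted p = 1.68e-06) in the authors' deposited table. Below these, the authors' deposited table lists the beta-tubulin Tubb2b (2.59 ± 0.39), the sulfotransferase Chst2 (2.47 ± 0.33), the F-box protein Fbxo2 (2.44 ± 0.41) and the surface antigen Ly6c1 (2.38 ± 0.39). The tetraspanin Cd63 (2.25 ± 0.37) and gelsolin, the actin-severing protein encoded by Gsn (2.23 ± 0.37), complete the 12 positive genes that the naming rule took from the authors' deposited table. The rule passes over microRNA names, and so over Mir155hg, a microRNA host gene at 2.46 ± 0.38 in the authors' deposited table (chosen after its value was seen). In all, 32 genes had a log2 fold change above 2.

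The 34 negative genes were weakly expressed. Their median baseMean was 73.7, against 798 for the positive genes, and the highest was 196. Cdh1, which encodes E-cadherin, had the largest negative fold in the authors' deposited table, a log2 fold change of -1.29 ± 0.44 (adjusted p = 0.0204). The others named include the antisense transcript Mccc1os (-1.15 ± 0.40), the sugar transporter Slc5a9 (-1.08 ± 0.43), the kinase Nrk (-1.06 ± 0.36) and the epoxide hydrolase Ephx2 (-1.04 ± 0.40) in the authors' deposited table. The protocadherin Pcdh19 (-1.03 ± 0.38), Hephl1 (-1.01 ± 0.38), the vomeronasal receptor Vmn2r102 (-1.01 ± 0.41) and the myosin Myh15 (-1.01 ± 0.35) followed in the authors' deposited table. The muscle membrane protein Sgcd (-0.99 ± 0.43), the proteoglycan Spock1 (-0.96 ± 0.39) and the lipid kinase Dgkb (-0.96 ± 0.38) complete the 12 from the authors' deposited table. No negative gene had an adjusted p below 0.0185 in the authors' deposited table. None belongs to any of the 50 fixed gene lists, whose 424 members in the table were all positive.

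**Figure D2:**
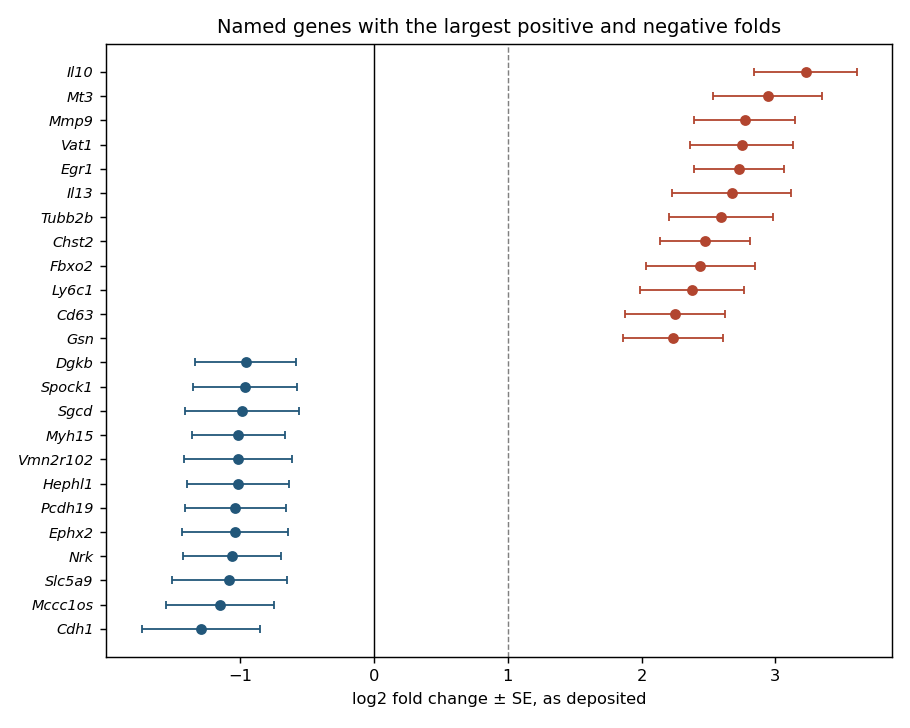
Log2 fold change as deposited (horizontal axis; points) with its SE (bars) for the 12 positive (red) and 12 negative genes (blue) with the largest folds under a fixed rule, which passes over gene model, microRNA, snoRNA and pseudogene names. The positive folds run from 2.23 to 3.23 and the negative ones from -0.96 to -1.29; the dashed line is the table's median of 1.00.

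The Th1, Th2, cytotoxic and inhibitory receptor lists had larger median folds than random lists of called genes. Of the Th2 list (type 2 helper cells), 9 of 17 members were called, with a median log2 fold change of 1.41. Beside Il10 and Il13, the authors' deposited table lists Il5 at 2.01 ± 0.49 and Il24 at 1.78 ± 0.42, while Gata3, the lineage's transcription factor, was at 1.03 ± 0.33. Of the Th1 list (type 1 helper cells), 11 of 17 members were called, with a median of 1.39. They include Tnf (1.80 ± 0.34), the transcription factor Tbx21 (1.72 ± 0.33) and the receptor chain Il12rb2 (1.58 ± 0.35) in the authors' deposited table. Ifng, which encodes the main Th1 cytokine, and Il2 are not among the genes called. Cytotoxic effector molecules had the highest median of all lists tested, 1.60 over 9 of 12 members. Among them were perforin, encoded by Prf1 (1.71 ± 0.38), and the granzymes Gzma (1.77 ± 0.43) and Gzmb (1.60 ± 0.39) in the authors' deposited table. Inhibitory receptors and related regulators had a median of 1.49 over 8 of 11 members. The repressor Prdm1 (1.85 ± 0.36), Lag3 (1.64 ± 0.35), Cd274 (1.58 ± 0.34) and Nfil3 (1.61 ± 0.37) were the members with the smallest p in the authors' deposited table. The medians of the Th1, cytotoxic and inhibitory lists exceeded those of all 10000 matched random lists (permutation, adjusted p = 0.00133 each), and that of the Th2 list exceeded 99.98% of them (permutation, adjusted p = 0.00343). Against an offset of 0.5, fewer members kept a higher fold: 2 of 9 for Th2, 2 of 11 for Th1, 0 of 9 for the cytotoxic and 1 of 8 for the inhibitory list. All members called in these lists passed when adjusted over the list alone, which tests against no change and also held for all called members of 38 of the 46 lists with any. Mitochondrially encoded transcripts, which vary with RNA quality, had a median of 1.46 in the same comparison.

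Immediate early genes, which are induced on activation, had a median log2 fold change of 1.40 over 11 of 18 members, above all random lists (permutation, adjusted p = 0.00133). They include Rgs1 (1.98 ± 0.39), Atf3 (1.66 ± 0.37) and Junb (1.64 ± 0.38) in the authors' deposited table. The T cell activation list had a median of 1.21 over 16 of 26 members (permutation, adjusted p = 0.0050). Beside Egr1, the members with the smallest p in the authors' deposited table were Egr2 (1.94 ± 0.34), Egr3 (1.52 ± 0.32) and Il2rb, a chain of the interleukin-2 receptor (1.56 ± 0.36). The regulatory T cell list had a median of 1.23 over 10 of 16 members (permutation, adjusted p = 0.0382), and this call was lost with the mean in place of the median (permutation, adjusted p = 0.0567). Ctla4, an inhibitory receptor of activated and regulatory T cells, was its leading member at 2.06 ± 0.39 in the authors' deposited table, with Entpd1 (1.40 ± 0.33), Tigit (1.35 ± 0.32) and Nrp1 (1.24 ± 0.32). Foxp3, the lineage's transcription factor, is not among the genes called. Lists that did not pass this test were T follicular helper genes (5 of 11 called, median 1.35, permutation adjusted p = 0.0502), IL-2 and STAT5 targets (8 of 13, median 1.19, permutation adjusted p = 0.0593) and Th17 genes (7 of 15, median 1.14). The same holds for NF-kB and TNF response genes (11 of 17, median 1.00), chemokine receptors and homing genes (8 of 14, median 1.00) and naive and central memory genes (10 of 14, median 0.96). With the mean in place of the median, IL-2 and STAT5 targets (permutation, adjusted p = 0.0096) and NF-kB genes (permutation, adjusted p = 0.0196) passed, and without matching T follicular helper genes did (permutation, adjusted p = 0.0392). Single members of these lists had large folds, such as Socs3 (2.05 ± 0.33), Gadd45g (2.07 ± 0.37) and Ier3 (1.97 ± 0.38) in the authors' deposited table.

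Hypoxia-inducible genes were called more completely than most lists. Of 16 targets of the transcription factor HIF1, 14 were called, with a median log2 fold change of 1.41, above all random lists (permutation, adjusted p = 0.00133). Hilpda, a lipid droplet protein (2.04 ± 0.42), Ankrd37 (1.92 ± 0.39), the prolyl hydroxylase Egln3 (1.86 ± 0.39) and the growth factor Vegfa (1.63 ± 0.34) had the smallest adjusted p among them in the authors' deposited table. Of 20 glycolysis genes, 16 were called, with a median of 1.15 (permutation, adjusted p = 0.0424). This call was lost when the statistic replaced the fold (permutation, adjusted p = 0.133) and without matching (permutation, adjusted p = 0.0582). Hexokinase 2, encoded by Hk2 (1.75 ± 0.38), and the glucose transporters Slc2a3 (1.71 ± 0.37) and Slc2a1 (1.67 ± 0.39) led the list in the authors' deposited table.

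The list of acetate and acetyl-CoA handling genes did not pass the list test, which compares called members with other called genes. Of 22 such genes, 7 were called, with a median log2 fold change of 1.04 (permutation, adjusted p = 0.835), and at least 4 of the 7 passed when adjusted over the list alone. The acetate receptor gene Ffar2 (1.61 ± 0.39, adjusted p = 0.00198) and the monocarboxylate transporters Slc16a3 (1.68 ± 0.43) and Slc16a1 (1.04 ± 0.43) were positive in the authors' deposited table. Acss2, which encodes a synthetase that turns acetate into acetyl-CoA, was at 0.82 ± 0.34 (adjusted p = 0.0440) in the authors' deposited table, above 8.61% of its genes. Acss1, Acly and Ffar3 are not among the genes called. Sterol and fatty acid synthesis genes (9 of 32 called, median 1.16), fatty acid oxidation (12 of 17, median 0.99), the TCA cycle (14 of 22, median 1.03) and nuclear genes of oxidative phosphorylation (14 of 26, median 1.05) did not pass the list test. Cholesterol efflux genes (4 of 9 called) were too few to test. Nor did chromatin enzymes pass, with 9 of 16 acetyltransferase genes called at a median of 0.90 and 12 of 18 deacetylase and sirtuin genes at 1.05.

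Lists of growth and division genes differed in the number of members called. Of 25 G2/M genes, 2 were called, Mki67 (0.94 ± 0.38) and Ube2c (0.91 ± 0.38) in the authors' deposited table, and neither is sure to pass when adjusted over the list alone. Of 30 G1/S and replication genes 6 were called (median 1.08), of 25 ATF4 and amino acid response genes 4, and of 24 MYC and ribosome biogenesis genes 8 (median 1.00). Adjusted over the list alone, at least 3 of the 6, 3 of the 4 and 0 of the 8 passed. Whether the other members were tested and missed the threshold, or were not tested, is not known. Ribosomal proteins (23 of 34 called, median 1.03) lay at the middle of the table. None of the remaining stress and signalling lists passed the list test. These were p53 targets (14 of 19 called, median 1.14), quiescence genes (5 of 14, 1.11), apoptosis regulators (7 of 15, 1.03), NRF2 targets (8 of 16, 1.18), heat shock (7 of 14, 1.11), the unfolded protein response (8 of 18, 0.99) and osmotic stress (8 of 15, 1.00). The others were the autophagy and lysosome list (17 of 21, 1.08), TGF-beta response (9 of 11, 1.04), type I interferon (19 of 30, 1.06) and interferon gamma and MHC genes (17 of 28, 1.08). For replication-dependent histones only 5 of 52 symbols could be matched (median 1.11), each of them in the table, so the share called is set by the matching and cannot be read.

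Transcripts that reflect the make-up of the RNA were positive too, where they were called. Mitochondrially encoded genes had a median log2 fold change of 1.46 over 7 of 13 members, above all random lists (permutation, adjusted p = 0.00133), led by mt-Nd6 (1.74 ± 0.41) and mt-Nd2 (1.69 ± 0.44) in the authors' deposited table. The mitochondrial ribosomal RNA mt-Rnr2 held 12.9% of the summed baseMean of the table and had a log2 fold change of 1.18 ± 0.40 in the authors' deposited table. The nuclear non-coding RNAs Malat1 (1.59 ± 0.31) and Neat1 (1.58 ± 0.31) were positive in the authors' deposited table, on a list that did not pass (6 of 16 called, median 1.10). T cell identity genes were called in 7 of 16 cases at a median of 0.92 (permutation, adjusted p = 0.233). Among them were Zap70 (1.23 ± 0.35) and Trac (0.94 ± 0.33) in the authors' deposited table. Of 80 markers of other cell types, 5 were called. They were Igkc (1.30 ± 0.47), Ms4a1 (1.11 ± 0.41) and Cd79b (0.94 ± 0.39) of B cells, Cxcr2 (1.18 ± 0.41) of neutrophils and Cd8b1 (1.09 ± 0.41) of CD8 T cells in the authors' deposited table. None of the 3 B cell genes is sure to pass when adjusted over the list alone. Outside the fixed lists, and chosen after their values were seen, Tnfrsf13c, the BAFF receptor of B cells (2.01 ± 0.38), and Cxcr1, a chemokine receptor of neutrophils (1.81 ± 0.36), had larger folds in the authors' deposited table. No member of the fixed lists for natural killer cells, for macrophages and dendritic cells, for erythroid cells or for stroma is among the genes called. This says nothing of markers outside those lists.

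**Figure D3:**
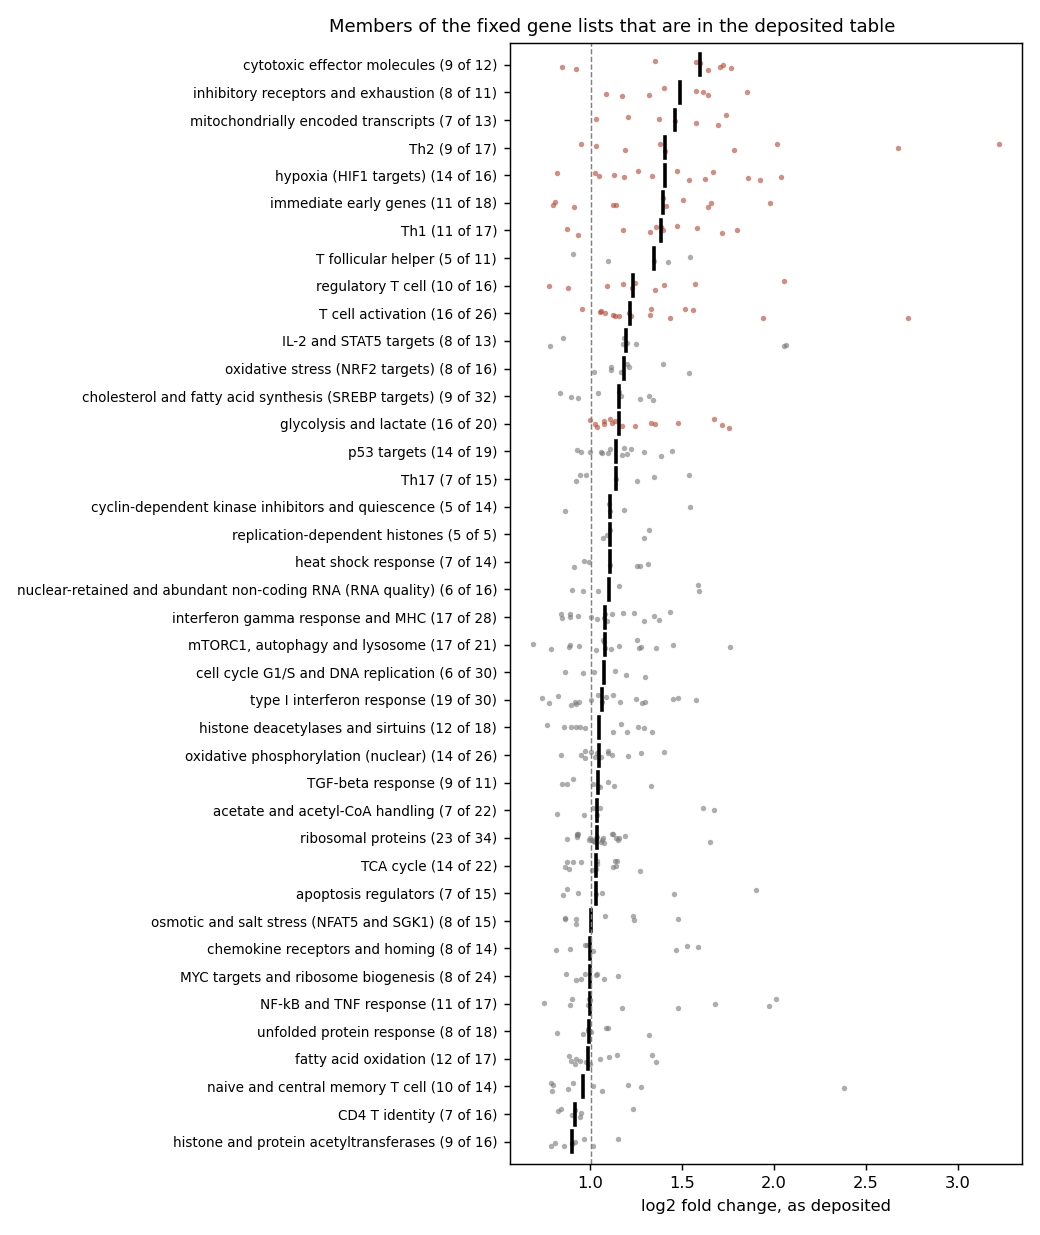
Log2 fold change as deposited (horizontal axis) of the members of 40 fixed gene lists (vertical axis, with the number of members in the table out of those matched); points are genes, black bars list medians and the dashed line the table's median of 1.00. Red marks the 10 lists whose median exceeded matched random lists at an adjusted permutation p under 0.05, from 1.15 for glycolysis to 1.60 for cytotoxic effector molecules.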

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

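All alternatives run were chosen after seeing the data, because those fixed before need values per sample. Not run were the other scalings (size factors, upper quartile, library totals), the filters on low counts, the other count tests, the minimum-fold test of the planned tool, pseudocounts, the removal of abundant RNAs before scaling, leaving out each replicate, and, for the lists, camera, fry and an estimated correlation. No paired analysis was possible because the table has no value per sample. The 6271 genes called became 1138 at an adjusted p under 0.01, 3176 with an absolute log2 fold change above 1, 381 in a Wald test against a fold of 1.2, and 4052 with a baseMean of at least 500. Positive genes (6237) became 1138, 3165, 381 and 4052, and negative genes (34) became 0, 11, 0 and 0, in that order. Each is fewer by construction, since a condition was added. Positive genes fell to 99 when folds were re-centred on 0.5 and to 7 on the table's median. Of 186 named genes with a positive fold, 30 passed on 0.5 and 156 did not. The count of called lists was 9 to 11 against 10, and 8 of the 10 held in all 4 alternatives. The exceptions were glycolysis and the regulatory T cell list. The depth of the libraries is unknown, so what depth limits cannot be stated.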

Other observations

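The tests of baseMean in the negative genes, of a common offset in 4 gene lists and of markers of other cell types were chosen after those values were seen, and the other tests of explanations were written before their own results were seen but after the table had been examined. The lists pooled in these tests were chosen after the results of the single lists were seen. All genes added here were chosen after their values were seen. The metallothioneins Mt1 (1.90 ± 0.45, SE) and Mt2 (1.83 ± 0.44), which bind zinc and copper, had large positive folds in the authors' deposited table, as Mt3 did. So did the transcription regulator Id2 (1.81 ± 0.40), the annexin Anxa1 (1.93 ± 0.41), S100a11 (1.88 ± 0.39), and the surface antigen Ly6a (1.85 ± 0.42) in the authors' deposited table. When the table was grouped by gene symbol root, none of 88 families with at least 8 members differed from matched random lists after adjustment, and 8 did at an unadjusted permutation p under 0.05. Interleukins and their receptors came nearest, with a median of 1.18 over 24 genes (permutation, adjusted p = 0.0704).

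The imbalance of 6237 positive and 34 negative genes is the pattern that most needs the counts behind it. Transcript length and GC content stay open. Over 5 equal groups of genes the lowest share of positive genes was 98.4%, in the longest genes, and 99.1% by GC content. With 34 negative genes no group could have fallen under 97.3%. The bound set for a bias could therefore not be reached, and the bound set for no bias was certain to be met. This test therefore decides nothing. The median log2 fold change fell from 1.09 in the shortest to 0.94 in the longest of these groups. The negative genes' median baseMean lay at percentile 1.96 of the table, and their exonic sequence was long, with a median of 8325 bp against 2047 bp in positive genes matched on baseMean, a ratio of 4.07 (permutation p = 2e-05, the smallest it can give). A background of reads spread over gene bodies, larger in the libraries of the fold's denominator, may give both and is offered as a hypothesis, while a length bias, a real change of most transcripts and 1 outlying library stay open, the last 2 untested without values per sample.

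Th1, Th2, cytotoxic and inhibitory genes had high folds in the table, beside mitochondrially encoded, immediate early and hypoxia genes, whose list medians of 1.46, 1.40 and 1.41 were above that of the Th1 list (1.39). Each of these 4 lists, fixed before the data were examined, stood above random lists matched on baseMean (largest permutation p, adjusted over 40 lists, 0.00343). This argues against larger folds at low expression, on their own, as the reason. The 4 lists were chosen after this comparison was seen, so it is no separate test of 1 offset for all genes. Gene by gene, 1 Th2 member and no Th1, cytotoxic or inhibitory member passed the adjusted 1-sided Wald test against the table's median. The folds lay above that median in 8 of 9 Th2, 9 of 11 Th1, 7 of 9 cytotoxic and 8 of 8 inhibitory members. The comparison with random lists takes genes as independent, so noise shared by the genes of a list stays open. Cells of another type cannot be told apart from a change in the T cells, because only 5 of 80 markers of other types are in the table and the values of the others were not seen. No biological explanation was tested.

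Cell cycle and ATF4 genes were scarce in the table, with 12 of 80 called (15%, exact 95% interval 8.0% to 24.7%), and hypoxia and glycolysis genes were frequent, with 30 of 36. These lists were picked for their low and high shares, so the exact tests run on the difference restate that choice and are void. MYC and ribosome biogenesis genes lay between them with 8 of 24, none of which is sure to pass when adjusted over the list alone. Members that were never tested could explain the low share: the 12 that were called had a median baseMean at the 78.1st percentile of the table, which says nothing of the missing ones. A missing gene that was tested can still have a fold as large as those listed, if its SE was larger.

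The median SE of the authors' deposited table was 0.36. Counting alone would give 0.042 at the table's median baseMean with 3 samples in each group. The 378 genes with a baseMean of at least 5000 had a median SE of 0.37 in the authors' deposited table. Large SEs are under-represented among listed genes, since the threshold removes them, so no relation of the SE to expression can be read from the table.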
